A study of Homo sapiens with 9 samples.

How the data were processed

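Total RNA of 9 libraries, 3 each of cord blood CD34 positive cells, BFU-E and CFU-E, was prepared with a TruSeq RNA kit, per the labels' protocols, which do not mention strand. Reads were processed with CASAVA 1.8.2, TopHat2 2.0.9 and Cuffdiff 2.1.1 on hg19, per the submitters' processing notes, and their settings are not given in the sources used here. The authors deposited 4 tables (genes, isoforms, start-site groups and coding sequences) with 1 estimated fragment signal, 1 variance of that signal and a status word per group, per the file headers. These signal values are not raw counts: they are fractional and their 75th percentiles over genes were 1454 in CD34, 1451 in BFU-E and 1453 in CFU-E although the totals differed, so they carry a scaling by the authors. The 3 libraries of a group had been combined before deposit, and 5 further columns in each of the 4 tables belong to no listed sample and were not used here. Nothing in the labels says whether the libraries came from separate donors or cultures.

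Groups were compared with a Wald test per gene computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The deposited signal was divided by median-of-ratios factors from 15020 genes with status OK and a value above 0 in all groups (1.20 for CD34, 1.05 for BFU-E and 0.852 for CFU-E). The log2 ratio of both groups was divided by its standard error, from the deposited variances by the delta method, and adjusted by the Benjamini-Hochberg method over the genes tested. A gene was tested if its status was OK in both groups, its value and variance were above 0 in both and its scaled value was at least 10 in 1 of them, and called at a false discovery rate of 0.05 and an absolute log2 fold change of at least 1. Genes at 0 in 1 group have no ratio. Among genes with status OK in both groups and a scaled value of at least 10 in the other group there were 773 at 0 in BFU-E only and 384 at 0 in CD34 only, 103 at 0 in CFU-E only and 188 at 0 in BFU-E only in the second comparison, and 435 at 0 in CFU-E only and 277 at 0 in CD34 only in the third. Some genes just above 0 in 1 group had standard errors too large to pass. SERPINA1, at 5387 in CD34 and 0.605 in BFU-E (-13.12 ± 8.91), counts as not called. In the 3 comparisons 884, 1287 and 1235 genes had an absolute log2 fold change of at least 1 and were not called. Genes of the X inactivation locus and those on Y were left out.

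The deposited variance sets the precision. Its square root was 28.3% to 31.5% of the value (medians over genes) between 10 and 100, 13.9% to 14.3% between 100 and 1000 and 9.02% to 9.44% between 1000 and 10000. For 93.1% to 94.2% of genes of 100 and more it lay within 1.5 times the median of genes of like value, so it mostly follows the value and is not a gene's own spread between libraries. For the 5 genes above 1000000 in CD34 its median was 0.685%, far below the rest, and standard errors of such genes are too small. The test was tested on simulated data with 200 changed genes per comparison: among genes changed by a log2 of 2 it recovered 87.9% in BFU-E against CD34 (15467 genes simulated), 80.6% in CFU-E against BFU-E (14585) and 88.9% in CFU-E against CD34 (15470), and at a log2 of 3 it recovered 91.8%, 92.9% and 96.0%, with 10, 14 and 8 false calls. The simulated values were drawn with the same deposited variances that the test was given. Few false calls therefore follow from the setting, and the error rate under real spread between libraries remains unknown.

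Before the data were examined, 31 gene lists, the tests, most of the alternatives and the rule for named genes were fixed. The rule takes, per comparison, the 10 largest and 10 smallest log2 fold changes among called genes with at least 500 in the higher and 10 in the lower group, leaving out uncharacterised loci and small RNAs, the 4 tested members of each list with the largest absolute change, a set of 18 marker genes, and 5 genes for isoforms; other names are said to be chosen afterwards. Some genes that the rule takes are not reported here. List medians were set against 10000 random lists of the same size matched on mean value in 20 bins. Isoforms were tied to genes through RefSeq accessions of a GRCh38.p14 gene table, used for names and neighbours only, for 38110 of 43497 isoforms, and their sums lay within 1% of the gene value for 15073 of 15430 genes. Alternatives were the values as deposited, equal totals, variances divided by 3, other filters, any status, other fold thresholds, and sums over isoforms. Variances times 4 and scaling from genes over 100 were added after the values had been seen.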

Results

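RNA of 3 groups of human cells from cord blood was sequenced: CD34 positive cells (CD34), burst-forming unit erythroid cells (BFU-E) and colony-forming unit erythroid cells (CFU-E), the earlier and the later progenitor that forms red cell colonies. Each group had 3 libraries, and the tables used here hold 1 deposited value per gene and group, so no value per library is used here. Summed over 23615 genes the deposited estimated fragments came to 101732766 in CD34, 75399033 in BFU-E and 47326172 in CFU-E. These totals follow the authors' own scaling, so the sequencing depth of each library is unknown. Values are estimated fragments after a further scaling between groups, and each log2 fold change is followed by ± its standard error, taken from the deposited model variance. "Rose" and "fell" are used of genes that passed a false discovery rate of 0.05 with an absolute log2 fold change of at least 1. Across 93 tests of a gene list in a comparison, the numbers of members that rose and fell adjusted over the list alone equalled those adjusted over all genes tested in 92. The exception was the list of G1 cyclins and CDK regulators in BFU-E against CD34, where 6 members instead of 5 fell when adjusted over the list alone.

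The first comparison set BFU-E against CD34. Each value is of a whole cell population. In every comparison a change within cells and a change in which cells were present therefore cannot be told apart. Genes of cell division rose together. Of 35 tested genes of G2 and mitosis 33 rose and none fell, among them MKI67, a marker of dividing cells, from 354 to 11095 (4.97 ± 0.22), the mitotic kinase gene TTK (4.70 ± 0.31), the spindle gene ASPM (5.13 ± 0.34) and the phosphatase gene CDC25C, which triggers entry into mitosis (6.22 ± 0.61). Of 36 genes of DNA replication 23 rose and none fell, led by CLSPN (3.80 ± 0.26) and MCM10 (3.28 ± 0.24). Of 42 genes of ribosome biogenesis 21 rose and 3 fell, with RRS1 at 3.60 ± 0.20 and SBDS at -2.67 ± 0.20. At the same time genes of stem cells, of the early stress response and of several other blood lineages fell.

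In all 2871 genes were higher and 3266 lower in BFU-E than in CD34 among 14909 tested. That is 41.2% of the genes tested, so a list with a like share called, in both directions, is not set apart by its counts. Among genes with at least 500 in the higher and 10 in the lower group, uncharacterised loci and small RNAs left out, the largest increases were those of CBS, which joins serine to homocysteine, from 29.0 to 3969.8 (7.10 ± 0.41), the serine synthesis gene PSAT1 (6.70 ± 0.29), the globin pseudogene HBBP1 (6.77 ± 0.55), CD180 (6.49 ± 0.51), CDC25C, TMEM177 (5.82 ± 0.45), the glycophorin gene GYPB (5.67 ± 0.51), CDCA2 (5.58 ± 0.38), SOCS1, an inhibitor of cytokine signalling (5.58 ± 0.49), and the nuclease gene EXO1 (5.41 ± 0.30). Under the same limits the largest decreases were those of the growth factor gene IGF2, from 37209.8 to 13.7 (-11.41 ± 0.58), PDE4B (-9.02 ± 0.45), the nuclear receptor gene NR4A1 (-8.09 ± 0.30), the platelet factor gene PF4 (-7.98 ± 0.48), MAFF (-7.72 ± 0.30), the complement receptor gene C5AR1 (-7.64 ± 0.49), S100A9 (-7.63 ± 0.41), the imprinted RNA gene H19 (-7.45 ± 0.38), GRASP (-7.39 ± 0.43) and SIK1 (-7.37 ± 0.31). IGF2 overlaps the readthrough gene INS-IGF2, and HBBP1 and GYPB resemble neighbouring genes, so their split of reads is uncertain. The same holds for CDC25C, H19 and MAFF, which overlap another gene in the annotation. Among genes named further on it holds for CISH, HIF1A, THBS1, PPOX, RBL2, TYMS, TUBB1, BAALC, CD1C and ALAS2.

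Erythroid regulators moved in both directions. KLF1, an activator of globin and membrane genes, rose from 935 to 12593 (3.75 ± 0.19), GATA1 rose (1.58 ± 0.16) and so did the erythropoietin receptor gene EPOR (1.47 ± 0.22) and the stem cell factor receptor gene KIT (2.38 ± 0.17). Of 31 tested erythroid transcription factors 5 rose and 7 fell, the latter including HIF1A (-5.07 ± 0.39), KLF3 (-3.50 ± 0.19) and BCL11A, a repressor of fetal globin (-2.50 ± 0.19). GATA2, TAL1 and MYB did not pass the test, at 18112, 5918 and 22304 in CD34 and 11421, 7508 and 30672 in BFU-E. Of 33 progenitor and myeloid factors 7 rose and 11 fell, with IRF4 at -5.91 ± 0.55, ELF1 at -5.46 ± 0.20 and BCL6 at -5.32 ± 0.31. Targets of erythropoietin and STAT5 split, 7 of 23 rising and 8 falling: CISH rose (3.87 ± 0.24) and SOCS3 fell (-3.01 ± 0.26). Of 30 cytokine and growth factor receptors 8 rose and 11 fell.

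Genes of the mature red cell moved both ways at this step. Of 20 genes of heme synthesis 4 rose, among them ALAS1 (2.32 ± 0.21), and 2 fell, while ALAS2, the erythroid form of its first enzyme, stood at 483 in CD34 and 452 in BFU-E and did not pass the test. Of 33 red cell membrane and blood group genes 9 rose and 7 fell, and of 22 genes of iron uptake and storage 9 rose and 5 fell, with the transferrin receptor gene TFRC at 1.88 ± 0.15 and the iron exporter gene SLC40A1 at 2.41 ± 0.16. Of 10 tested globin and globin chaperone genes 3 rose and 3 fell. HBD rose (4.31 ± 0.19), HBA1 (-3.26 ± 0.21) and HBA2 (-6.78 ± 0.39) fell, and HBB was at 10418 and 6356 with no call. HBA1 and HBA2 are near-identical, so the division of reads between them is uncertain. Such a division alone would not lower both. How reads that match both were handled is not known, so no fall of alpha globin can be read from these values.

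Stem and multipotent progenitor genes fell in 15 of 30 tested members and rose in none, with HOPX at -4.02 ± 0.21, HLF at -3.83 ± 0.27, AVP at -4.21 ± 0.33 and MSI2 at -2.85 ± 0.19. Their median log2 fold change of -1.0 lay below those of 10000 random lists matched on mean value. Immediate early and handling stress genes fell in 16 of 23 members and rose in 3, with NR4A2 at -9.98 ± 0.72, ATF3 at -5.38 ± 0.28 and EGR3 at -5.45 ± 0.69. Of 18 genes of the glucocorticoid response and progenitor self-renewal 13 fell and 1 rose, with TSC22D3 from 125393 to 1626 (-6.27 ± 0.18) and PER1 at -5.01 ± 0.22.

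Markers of other blood cells also separated the groups. Megakaryocyte genes fell in 14 of 19 tested members and rose in 1, with the platelet gene PPBP at 10858 in CD34 (-6.95 ± 0.31) and THBS1 at -5.82 ± 0.22. B lymphoid genes fell in 11 of 14, with CD22 at -5.98 ± 0.75 and DNTT at -4.90 ± 0.41. T and NK genes fell in 10 of 15 and rose in 1, with CD3E at -4.55 ± 0.35 and GNLY at -5.18 ± 0.42. Dendritic genes fell in 7 of 10 and endothelial and stromal genes in 8 of 12 with 1 rising. Granulocyte and monocyte genes fell in 13 of 24 and rose in 6, with FCN1 at -7.30 ± 0.47 and VCAN at -6.25 ± 0.68. Mast cell, basophil and eosinophil genes rose in 11 of 16 and fell in none, with EPX at 3.44 ± 0.21, CLC at 3.32 ± 0.18 and KRT1 at 3.40 ± 0.47. MPO and PRG2, granule genes singled out for their level after their values were seen, reached 146139 and 158973 in BFU-E.

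Cholesterol synthesis genes rose in 9 of 24 members and fell in 1, led by CYP51A1 (2.46 ± 0.17). MHC class II genes fell in 6 of 10, CD74 by -1.36 ± 0.15. Adhesion genes fell in 9 of 27 and rose in 6, with ICAM1 at -3.20 ± 0.27 and CDH1 at 3.44 ± 0.30. Apoptosis regulators rose in 11 of 33 and fell in 6, among them MCL1 (-3.52 ± 0.16). The G1 regulators rose in 7 of 27 and fell in 5, with CDKN1A, an inhibitor of the cell cycle, at -6.12 ± 0.31. Chromatin modifiers rose in 9 of 37 and fell in 3, with EED at 4.06 ± 0.26. Oxidative phosphorylation genes rose in 6 of 35 and fell in 5, with NDUFB3 at 2.15 ± 0.19. Glycolysis genes rose in 2 of 22 and fell in 3, with SLC2A3 at -3.08 ± 0.18, and autophagy genes rose in 1 of 24 and fell in 5, with GABARAPL1 at -4.14 ± 0.23. Sorting surface markers, which are no independent finding between sorted cells, rose in 2 of 14 and fell in 6. Their list includes the CD34, CD36, TFRC, KIT and PTPRC genes, so the same limit holds wherever these are named. Of the genes that passed, 46.8% were higher in BFU-E, against 58.8% with groups scaled to equal totals and 36.5% with scaling from genes over 100, which shift all log2 fold changes by 0.25 and -0.22.

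The second comparison, CFU-E against BFU-E, followed the step from the earlier to the later progenitor. Red cell genes rose and stem cell genes fell. Of 11 tested globin and globin chaperone genes 9 rose and none fell: HBB, adult beta globin, went from 6356 to 83164 (3.71 ± 0.16), the fetal globin gene HBG2 from 7663 to 120084 (3.97 ± 0.16) and the alpha-globin chaperone gene AHSP from 451 to 13939 (4.95 ± 0.21). HBG1 rose as well (2.37 ± 0.18), though reads are hard to divide between HBG1 and HBG2. The gene of the stem cell marker CD34, used in sorting, fell from 11994 to 45.1 (-8.05 ± 0.39).

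In all 2907 genes were higher and 2661 lower in CFU-E than in BFU-E among 14746 tested, which is 37.8% of them. Under the same limits on values the largest increases were those of S100A9 (6.65 ± 0.41), DDI2 (6.40 ± 0.88), IPO11 (6.32 ± 0.67), the red cell spectrin gene SPTB, from 50.02 to 3852 (6.27 ± 0.36), SLC2A14 (6.21 ± 0.49), GALNT5 (5.63 ± 0.49), the fatty acid receptor gene CD36 (5.62 ± 0.25), ZKSCAN8 (5.59 ± 0.39), the red cell pyruvate kinase gene PKLR (5.58 ± 0.27) and the dendritic cell lectin gene CLEC10A (5.42 ± 0.31). After CD34 the largest decreases under these limits were those of TIAF1 (-7.74 ± 1.61), MFAP4 (-6.58 ± 1.54), BAHCC1 (-6.42 ± 0.63), SLC2A5 (-6.39 ± 0.47), MN1 (-6.08 ± 0.63), MDK (-6.07 ± 0.67), SPNS2 (-5.90 ± 1.82) and ASCL2 (-5.89 ± 0.69). DDI2, IPO11, SPTB, PKLR, TIAF1, MFAP4, MDK and SPNS2 overlap another gene with signal, and SLC2A14 is a near copy of SLC2A3, so these values are uncertain. With standard errors doubled, TIAF1, MFAP4 and SPNS2 no longer passed. CD36 is on the list of sorting markers, so its rise is no independent finding.

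Of 20 heme synthesis genes 10 rose and none fell, with ALAS2 from 452 to 4451 (3.30 ± 0.23), the ferrochelatase gene FECH at 2.92 ± 0.17, ABCB10 at 3.43 ± 0.19 and PPOX at 2.53 ± 0.20. Red cell membrane and blood group genes rose in 21 of 33 and fell in 3, with RHAG at 5.38 ± 0.21, EPB42 at 4.61 ± 0.29 and CA2 at 5.02 ± 0.34. Iron genes rose in 8 of 22 and fell in 1, TFRC reaching 176451 (2.49 ± 0.15) and TFR2 rising by 2.51 ± 0.16. PTPRC, the common white cell antigen, rose from 1627 to 7681 (2.24 ± 0.19), and sorting surface markers as a list rose in 9 of 13 and fell in 2.

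Of 32 erythroid transcription factors 12 rose and 3 fell, with HIF1A at 3.58 ± 0.39, NFE2L2 at 3.45 ± 0.21 and KLF1 at 1.08 ± 0.15, the last of which no longer passed with the values as deposited (0.78) or with scaling from genes over 100 (0.89). EPOR (1.57 ± 0.19) and KIT (1.67 ± 0.15) rose, whereas GATA1, TAL1, MYB and BCL11A did not pass the test at 15432, 11903, 31209 and 1199. TAL1 passed with groups scaled to equal totals (1.03). GATA2 fell from 11421 to 2170 (-2.40 ± 0.18). Of 33 progenitor and myeloid factors 20 fell and 5 rose, with CEBPE at -5.98 ± 0.78, GFI1 at -4.58 ± 0.29 and ERG at -4.49 ± 0.31. Stem and multipotent progenitor genes fell in 19 of 28 members and rose in none, with PROM1 at -10.03 ± 1.34, SPINK2 at -8.85 ± 0.87 and BAALC at -8.85 ± 0.90, and their median of -3.82 lay below those of the matched random lists.

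G2 and mitosis genes rose in 8 of 35 and fell in 4, with BUB1 at 2.25 ± 0.17 and HMMR at 2.65 ± 0.19, while MKI67 fell (-2.85 ± 0.19). DNA replication genes rose in 6 of 36 and fell in 2, with TYMS at 2.06 ± 0.41. The G1 regulators rose in 13 of 27 and fell in 4, with the inhibitor gene CDKN1C at -5.72 ± 0.65 and RBL2 at 2.83 ± 0.22. Ribosome biogenesis genes rose in 9 of 42 and fell in 2, with DDX21 at 2.44 ± 0.16. Cholesterol synthesis genes rose in 7 of 24 and fell in 1, with SQLE at 1.70 ± 0.18, and glycolysis genes rose in 4 of 22 and fell in 1, with HK1 at 1.51 ± 0.16. Oxidative phosphorylation genes rose in 9 of 34 and fell in 6, with SDHD at 2.01 ± 0.17 and COX6C at -1.91 ± 0.16. Autophagy genes rose in 5 of 24 and fell in 3, apoptosis regulators rose in 6 of 33 and fell in 3 with BCL2 at -2.09 ± 0.20, and chromatin modifiers rose in 5 of 37 and fell in 6 with DNMT3A at -2.39 ± 0.22.

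Receptor genes rose in 9 of 31 and fell in 14, with FLT3 at -3.68 ± 0.36, and targets of erythropoietin and STAT5 rose in 3 of 23 and fell in 4, with JAK2 at 2.37 ± 0.21 and SOCS1 at -3.45 ± 0.35. Genes of the glucocorticoid response and progenitor self-renewal rose in 7 of 18 and fell in 2, with HIF1A again at 3.58 ± 0.39, DUSP1 at -3.05 ± 0.20 and PPARA at 2.63 ± 0.21. Immediate early genes fell in 12 of 21 and rose in 1, with FOSB at -5.31 ± 0.36 and FOS at -3.68 ± 0.18. Adhesion genes fell in 11 of 25 and rose in 7, with PECAM1 at -3.69 ± 0.22 and CDH1 at 3.67 ± 0.18, and MHC class II genes fell in 4 of 10, CD74 by -1.91 ± 0.15.

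Markers of other blood cells moved apart at this step. Mast cell, basophil and eosinophil genes fell in 12 of 16 and rose in 1, with IL5RA at -4.10 ± 0.47 and CLC at -4.0 ± 0.20. Of 24 granulocyte and monocyte genes 12 fell and 10 rose: the neutrophil granule gene PRTN3 fell (-5.72 ± 0.24), and VCAN (7.80 ± 0.68) and S100A9 rose, with LYZ, named after its value was seen, going from 9372 to 95706. The median of that list was -0.48 and turned to 0.30 among genes of at least 100. Dendritic genes rose in 2 of 10 and fell in 4, with CD1C at 4.64 ± 0.49 and CLEC9A at -2.30 ± 0.48, the latter not passing with standard errors doubled. B lymphoid genes fell in 5 of 10 and rose in 1, with CD79A at -4.17 ± 0.48. T and NK genes fell in 5 of 11 and rose in 1, with NKG7 at -4.22 ± 0.26. Endothelial and stromal genes fell in 9 of 13, with COL1A2 at -4.36 ± 0.83, and megakaryocyte genes rose in 6 of 19 and fell in 7, with TUBB1 at 2.45 ± 0.30. Of the genes that passed, 52.2% were higher in CFU-E, against 36.4% with the values as deposited, 70.01% with equal totals and 42.1% with scaling from genes over 100, which shift all log2 fold changes by -0.30, 0.37 and -0.19.

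**Figure D1:**
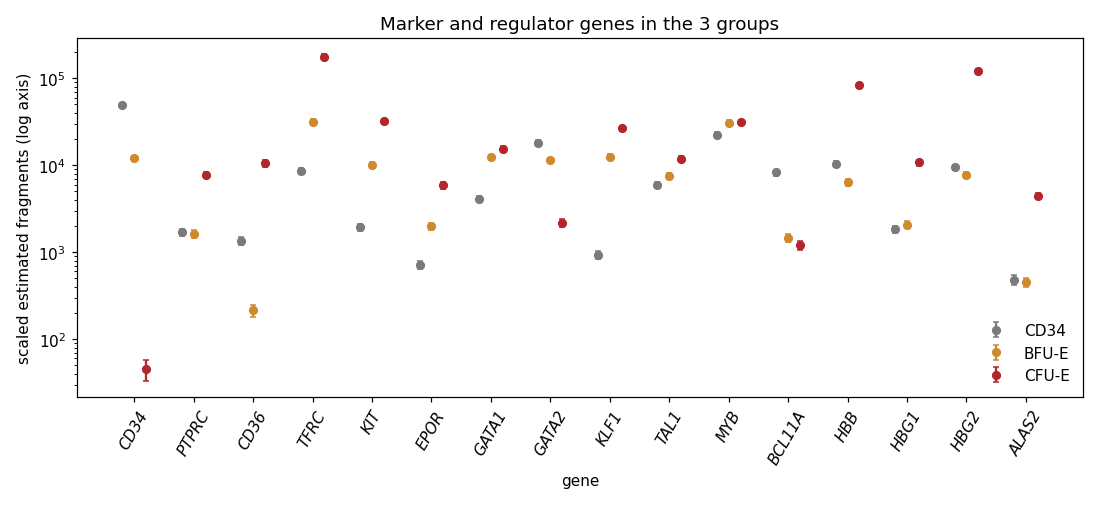
Scaled estimated fragments of 16 marker and regulator genes (log axis) in CD34, BFU-E and CFU-E; points are the group values and bars the square root of the deposited variance. TFRC reached 176451 in CFU-E and the CD34 gene 45.1.

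**Figure D2:**
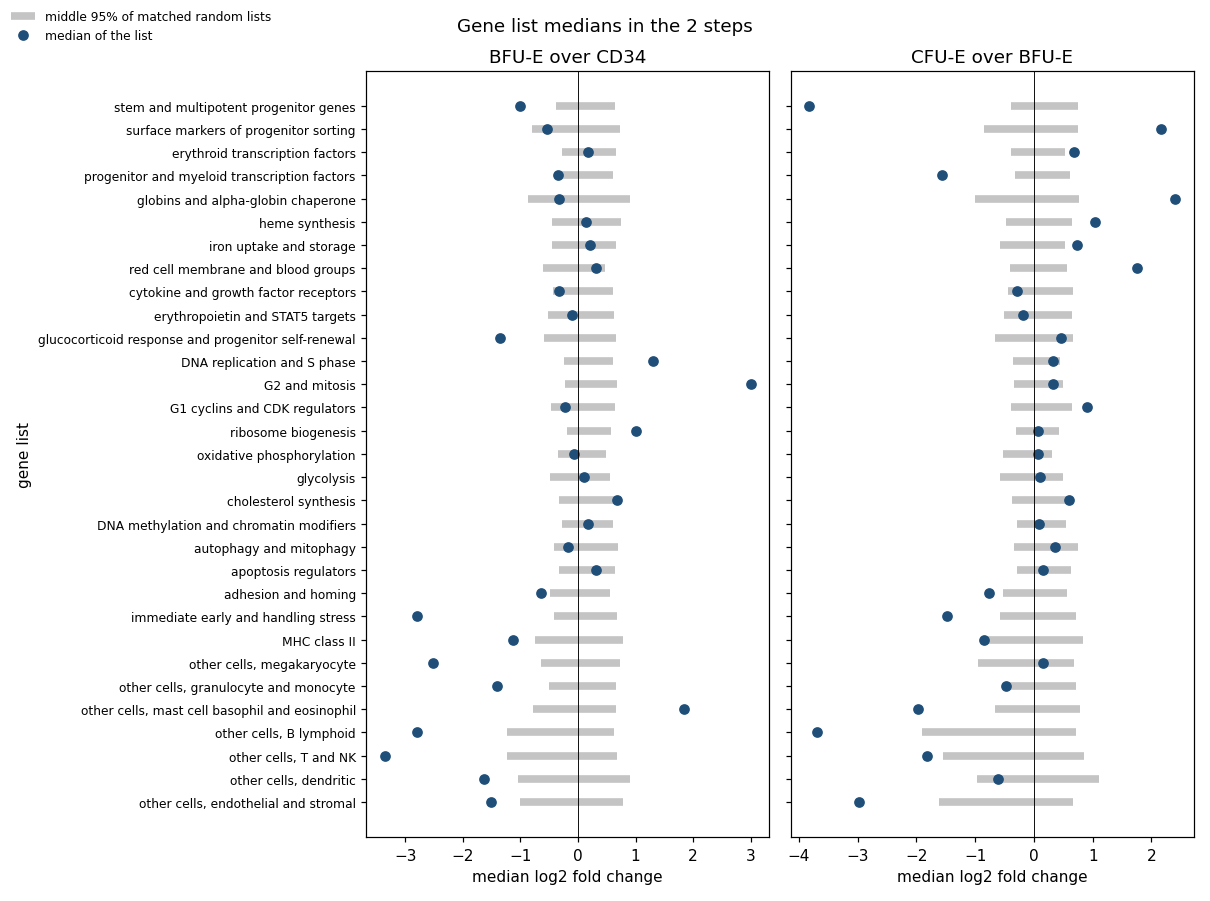
Median log2 fold change of each of 31 gene lists in BFU-E over CD34 (left) and CFU-E over BFU-E (right), as points, with the middle 95% of medians of 10000 random lists matched on mean value as grey bars. G2 and mitosis genes had a median of 3.0 in the first step and 0.32 in the second, and stem and multipotent progenitor genes -1.0 and -3.82.

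**Figure D3:**
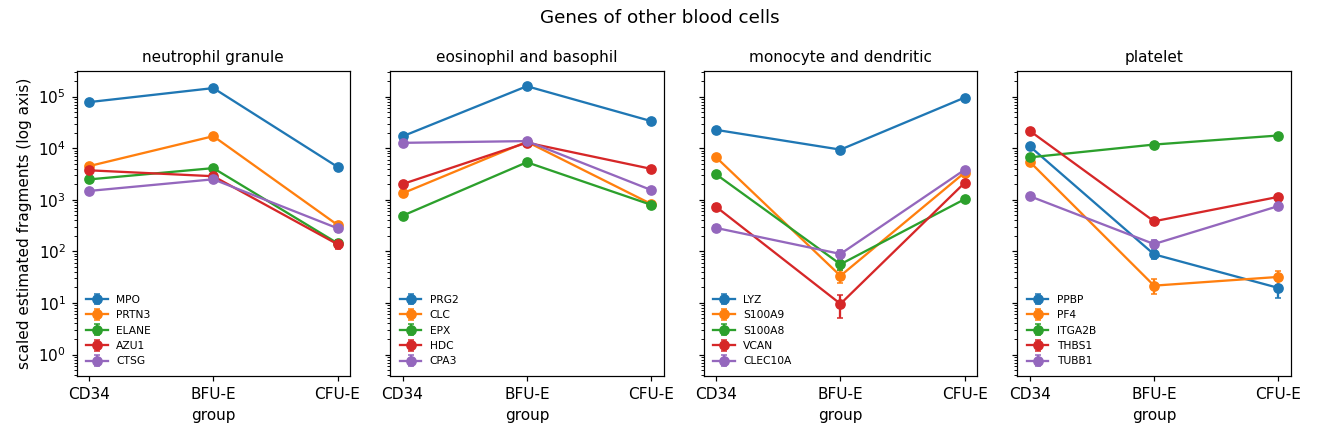
Scaled estimated fragments (log axis) of 20 genes of other blood cells in CD34, BFU-E and CFU-E, chosen for display after their values were seen; bars are the square root of the deposited variance. MPO fell to 4337 in CFU-E, while LYZ reached 95706.

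The third comparison set both ends of the series against each other. Genes of the red cell, of heme and of division were higher in CFU-E, and stem cell genes were lower. TFRC rose from 8586 to 176451 (4.36 ± 0.16), KLF1 by 4.83 ± 0.19, KIT by 4.04 ± 0.16, EPOR by 3.04 ± 0.20, GATA1 by 1.90 ± 0.16 and MYC by 4.13 ± 0.16. The CD34 gene fell from 48872 to 45.1 (-10.08 ± 0.39), SPINK2 by -11.21 ± 0.87, GATA2 by -3.06 ± 0.18 and BCL11A by -2.78 ± 0.20. TFRC, KIT and the CD34 gene are on the list of sorting markers, so their changes are no independent finding.

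In all 3969 genes were higher and 3862 lower in CFU-E than in CD34 among 15166 tested, which is 51.6% of them. Under the same limits on values the largest increases were those of HBBP1 (8.15 ± 0.54), CBS (8.0 ± 0.41), PSAT1 (7.53 ± 0.29), the cadherin gene CDH1, from 112 to 15475 (7.11 ± 0.28), SLC2A14 (6.83 ± 0.54), CDC25C (6.58 ± 0.61), IGSF3 (6.40 ± 0.56), GALNT5 (6.34 ± 0.56), the glycine transporter gene SLC6A9 (6.28 ± 1.23) and NMU (6.24 ± 0.36). After CD34 the largest decreases under these limits were those of NR4A1 (-10.01 ± 0.47), MDK (-9.59 ± 0.66), TSC22D3 (-9.26 ± 0.26), PPBP (-9.12 ± 0.53), PDE4B (-9.04 ± 0.49), FOSB (-8.11 ± 0.35), the B cell receptor gene CD79A (-8.03 ± 0.46), MAFF (-7.92 ± 0.32) and MYL9 (-7.92 ± 0.69). SLC6A9 overlaps CCDC24 and MDK overlaps CHRM4, so both are uncertain.

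Stem and multipotent progenitor genes fell in 25 of 28 and rose in none, progenitor and myeloid factors fell in 24 of 33 and rose in 4, and immediate early genes fell in 18 of 23 and rose in 1. G2 and mitosis genes rose in 34 of 35 with none falling, TOP2A by 5.58 ± 0.20, and DNA replication genes in 32 of 36 with none falling. Heme synthesis genes rose in 15 of 20 and fell in 1, red cell membrane genes rose in 22 of 33 and fell in 2, with RHAG at 5.95 ± 0.22. Globin genes rose in 8 of 11 and fell in 2, with HBE1 at 5.65 ± 0.34 and HBA2 at -4.37 ± 0.27. The handling of reads that match both HBA2 and its near-identical copy is not known, so no fall of alpha globin can be read from this value. Iron genes rose in 12 of 22 and fell in 3, ribosome biogenesis genes rose in 21 of 42 and fell in 2, with POLR1A at 2.92 ± 0.22. Cholesterol synthesis genes rose in 16 of 24 and fell in 1, and chromatin modifiers rose in 15 of 37 and fell in 4, with DNMT1 at 2.22 ± 0.18. Receptor genes rose in 8 of 30 and fell in 11, with CXCR4 at -4.72 ± 0.18. Among markers of other cells megakaryocyte genes fell in 13 of 19 and rose in 2, granulocyte and monocyte genes fell in 14 of 24 and rose in 3. B lymphoid genes fell in 8 of 11, T and NK genes fell in 11 of 16 and rose in 1, and mast cell, basophil and eosinophil genes fell in 5 of 16 and rose in 2. MYB did not pass, at 22304 and 31209, and passed with equal totals. TAL1 rose by 1.01 ± 0.17 but did not pass with the values as deposited (0.52) or with scaling from genes over 100 (0.60). Of the genes that passed, 50.7% were higher in CFU-E, against 33.4% with the values as deposited, 69.9% with equal totals and 36.3% with scaling from genes over 100, which shift all log2 fold changes by -0.49, 0.62 and -0.41.

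Both steps together were counted over 14290 genes tested in each. Genes that fell and then rose numbered 899, against 583 for independent lists, and included CD36, S100A9, VCAN, CA2 and HIF1A. Genes that rose and then fell numbered 650, against 521, and included SOCS1, CLC, PRTN3 and MKI67. A continued rise was found in 375, against 574, among them TFRC, KLF1, KIT, EPOR and CDH1, and a continued fall in 550, against 530, among them the CD34 gene, TSC22D3 and CD74. With the values as deposited a continued fall was found in 814, against 850, with scaling from genes over 100 in 771, against 786, with no fold threshold in 1055, against 1162, and with no filter on low values in 545, against 548. CD36, TFRC, KIT and the CD34 gene are on the list of sorting markers, so their patterns are no independent finding. The BFU-E values enter both steps, which are therefore not independent. Simulated groups with no change that shared these values gave 0 genes in each pattern, which leaves open how far the shared values add to the patterns among genes that did change.

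IL3RA, the receptor gene for interleukin 3 and a sorting marker, was listed at 0 in all groups. It lies in the segment that both sex chromosomes carry, where 14 of 15 genes were listed under 10 in all groups, so no level of IL3RA is given. Several genes were listed at 0 in 1 group only and have no fold change. Chosen after their values were seen, TREM1 at 1795 and the platelet gene TREML1 at 906 in CD34 were listed at 0 in BFU-E, VPREB1 at 595 in BFU-E was listed at 0 in CFU-E, and MGP at 2051, AVP at 1405 and CD3E at 1388 in CD34 were listed at 0 in CFU-E.

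Isoform shares differed by at least 25 percentage points in a large part of the genes with 2 or more isoforms and a summed value of at least 500 in both groups: 1671 of 3457 genes between BFU-E and CD34, 2148 of 3583 between CFU-E and BFU-E and 1373 of 3431 between CFU-E and CD34. No test of a share was possible, since the tables hold no covariance between isoforms, and values of single isoforms were not tested. The largest differences were complete or nearly complete exchanges. In BFU-E against CD34 they were those of CLEC2D, GTF2H3, CMPK1, XIAP and POLD3. The isoform with 100% of CMPK1 in CD34 had 0% in BFU-E. In CFU-E against BFU-E they were those of PPP3CA, UGDH, UQCC, POLD3 and PSMD12, and of the POLD3 isoforms at 0% in BFU-E, the coding one held 77.1% in CD34 and 98.2% in CFU-E and a non-coding one 22.9% and 1.8%. In CFU-E against CD34 they were those of UQCC, TRIM22, BBS9, TMEM39A and RPS6KB1.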

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

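Variances times 4 and scaling from genes over 100 were chosen after seeing the data. No paired analysis was possible because the deposited columns carry no replicate number. Leaving out each replicate, a replicate block and count models on libraries were not run, as the tables hold 1 value per group, and other splits of the libraries cannot be made for the same reason. With no fold threshold 4661 genes were higher in BFU-E than in CD34 and 4644 higher in CFU-E than in BFU-E, by construction. At an absolute log2 of at least 2 the counts were 975 higher and 1546 lower in BFU-E than in CD34, 960 higher and 1201 lower in CFU-E than in BFU-E, and 1620 higher and 2358 lower in CFU-E than in CD34. With variances times 4 the lower genes numbered 1964, 1549 and 2372 in these comparisons. In CFU-E against CD34 the values as deposited gave 2630 higher genes, and equal totals gave 5963 higher and 2570 lower, shifts that the scaling factors make for all genes alike. The other counts in these comparisons stayed within 1.5 times. Sums over isoforms gave calls in the opposite direction for 6 genes called higher and 6 called lower in BFU-E against CD34, 2 and 6 in CFU-E against BFU-E, and 2 and 3 in CFU-E against CD34.

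Genes rising in both steps numbered 179 with the values as deposited, 852 with equal totals and 216 with scaling from genes over 100, and genes falling in both 322 with equal totals. With no fold threshold the patterns held 1350 rising in both, 1597 rising then falling, 1653 falling then rising and 1055 falling in both. At an absolute log2 of at least 2 they held 37, 127, 271 and 143, and with variances times 4 they held 233, 409, 507 and 216.

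Named genes that changed sign were mostly near 0: in BFU-E against CD34, PTPRC at 0.18 and ALAS2 at 0.15 with equal totals, and HBG1 at -0.00180 as deposited and -0.0332 with scaling from genes over 100; in CFU-E against BFU-E, MYB at -0.28 as deposited and -0.16 with scaling from genes over 100, and BCL11A at 0.0869 with equal totals; in CFU-E against CD34, MYB at -0.00429 as deposited. None of these passed the test with the chosen scaling in these comparisons. The median of the granulocyte and monocyte list in CFU-E against BFU-E turned to 0.30 among genes of at least 100, and that of the receptor list in CFU-E against CD34 to 0.0568 with equal totals. The latter is the shift of 0.62 that this scaling gives all genes, and the cause of the former was not tested. Each scaling shifts the medians of lists as it shifts all genes. In BFU-E against CD34, CFU-E against BFU-E and CFU-E against CD34 this changed the sign of the median in 4, 2 and 4 of 31 lists with equal totals, 4, 6 and 2 as deposited and 5, 6 and 2 with scaling from genes over 100. Apart from the receptor list in CFU-E against CD34, the medians of these lists lay within the middle 95% of those of random lists. Depth per library is unknown, which limits what can be said of genes with values near 10.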

Other observations

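The lists in this part were written after the main results were seen, and so were the tests of scaling, that of isoform shares returning in CFU-E and that of short transcripts between BFU-E and CFU-E. Of 19 tested genes of serine, glycine and 1-carbon metabolism 15 rose and 1 fell between CD34 and BFU-E. The list was prompted by CBS, PSAT1 and SLC6A9, and without these 3 genes 12 of 16 rose and 1 fell. PHGDH, the entry enzyme of serine synthesis, went from 5667 to 26403 (2.22 ± 0.16), the folate enzyme gene MTHFD2 rose by 1.8 ± 0.16, the asparagine synthetase gene ASNS by 2.85 ± 0.21 and the glutamine transporter gene SLC1A5 by 2.69 ± 0.17. The list is wider than its name: ASNS and the amino acid transporter genes SLC1A5, SLC7A5 and SLC3A2 are not particular to these pathways. Of them only SLC3A2 did not pass in BFU-E against CD34. In CFU-E against BFU-E 6 of 19 rose and 2 fell. Genes of fetal growth did not move together: IGF2 and H19 fell as described, IGF2BP1 rose (2.57 ± 0.19), and LIN28B was at 594 in CD34, 576 in BFU-E and 1198 in CFU-E.

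Ribosomal protein genes held 34.7% of all deposited values in CD34, 27.1% in BFU-E and 14.6% in CFU-E, and 74 of 76 were lower in CFU-E than in CD34 with none higher, at a median log2 of -1.96. That median differed by -1.57 from that of matched random lists, which share an error of scaling that is the same for all genes. This argues against such an error as the whole cause. Matching in 20 bins leaves the highest values loosely matched, so an error that depends on the value is not excluded. Other small proteins had a median of -0.18 (quartiles -0.88 and 0.44, against -2.22 and -1.58 for ribosomal proteins). Of 42 tested, 6 fell and 2 rose between CD34 and CFU-E, so the fall was not shared by all genes of small proteins. Transcript lengths were not measured and the list includes proteasome subunits, so a loss of short transcripts in general is not excluded. This list was not flat over both steps: between CD34 and BFU-E its median was 0.63, with 13 of 42 rising and 3 falling. Between BFU-E and CFU-E the median of these other small proteins was -0.87 (quartiles -1.19 and -0.38, against a median of -1.37 and quartiles of -1.76 and -0.70 for ribosomal proteins), so such a loss may account for a part of that step. The 27 ribosomal protein genes with at most 10 pseudogenes had a median of -1.98, which argues against reads shared with pseudogenes as the whole cause, and no biological explanation was tested. Of 20 translation factor genes 11 were lower and 2 higher in CFU-E than in CD34, at a median of -1.10.

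Monocyte and dendritic cell genes higher in CFU-E than in BFU-E could come from scaling or from other cells in the libraries. All 12 members of the granulocyte and monocyte and the dendritic lists that rose still passed with the values as deposited. Of all 2907 genes that rose, 2049 still passed. Those values shift all log2 fold changes by -0.30, so this argues only against an error of scaling of about that size. In a list of abundant genes of monocytes, macrophages and dendritic cells 12 of 25 tested members rose and 2 fell. More than 12 were to rise if such cells were the source. MRC1, C1QA and C1QB of this list were at 0 in BFU-E, so they had no ratio, and were at 219, 106 and 22.1 in CFU-E. Counted as risen they would take the list over that bar, so the outcome turns on how genes at 0 are treated. Of the 25 tested members 0 were in a list fixed earlier and 13 had at least 500 in BFU-E. APOE rose to 28307 and PSAP was at 64962, whereas TYROBP was at 1214 and LST1 fell to 748. The 2 members that fell, LST1 and FCER1G, were already at 3531 and 1637 in BFU-E, so their fall does not argue against such cells as the source. RNA from such cells and a change within the progenitors cannot be told apart, since each value is of a whole cell population.

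Isoform shares differed between BFU-E and CD34 in 40.3% of 313 genes of 10000 and more in both groups, against 52.7% of 243 genes of 500 to 1000. A share above 39.5% was to argue against few fragments as the cause, and it was exceeded by 0.749 ± 3.67 percentage points (standard error), so few fragments may account for a part. Of 1587 genes that differed between BFU-E and CD34, 48.8% did not differ between CFU-E and CD34, against 60.4% of all 3260 genes. A property of BFU-E alone and shifts in each group cannot be told apart without values per library.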
